A study of Homo sapiens with 32 samples.

How the data were processed

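Nascent RNA was measured in HUH7 cells by EU labelling and sequencing. Per the labels' protocols, cells were held in 2 mM thymidine for 24 hours, released for 2 hours, treated with nocodazole at 0.06 ug/mL for 16 hours and collected by shake-off, then washed and replated. A pulse of 0.5 mM EU lasted 40 minutes, biotin was attached to EU by click chemistry, and the captured RNA was made into stranded libraries depleted of ribosomal RNA. Whether the pulse began or ended at the stated time is not given in the sources used here. The labels list 32 samples in 11 groups: 6 release times and an asynchronous culture with 3 samples each, an unlabelled control, and a later set of mitotic, asynchronous and unlabelled samples with spike-in RNA.

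Per the file headers, the deposited values are FPKM per RefSeq transcript, with 1 column for each of 7 groups and no column per library. The unlabelled and spike-in groups were not analysed here, so no background was measured beside these values. The submitters' processing notes name bcl2fastq, Bowtie2 2.2.9, TopHat, bedtools and the genome build hg19. The role of each aligner, the counting method, its use of strand, the annotation version, any background subtraction, how libraries were pooled, and whether the asynchronous column includes the spike-in set are not given in the sources used here. The table held 48205 transcripts with 32586 distinct sets of values, and none was at 0 in every group. Its order followed the ratio of 0 minutes to the asynchronous culture in 99.99% of neighbouring pairs.

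Transcripts were matched to gene symbols through a RefSeq gene table of the assembly GRCh38.p14, used for names alone. Of the transcripts, 47127 (97.8%) matched, giving 24242 genes, and 1078 did not. The references are of GRCh38 while the authors' build is hg19, and the table gives no positions, so no coordinates are printed. A gene's value was the mean over the distinct values of its transcripts, with 1 value for 19013 genes and several for 5229. Genes with at least 1 FPKM in at least 3 groups were kept, 22940 in number, and 1302 were left out. Fold differences were taken on log2(FPKM + 1), which understates the difference of low genes. Genes at least 2-fold apart were counted, and each list median is given relative to the median over all kept genes.

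The design fixed before the data were examined planned moderated tests with limma on values per library and camera for gene lists. With 1 pooled value per group, no test could be run and no p-value, error or number of replicates stands behind any difference. Size was described instead. The authors' FPKM are not counts, and read totals are not given, but low values in a column repeated in steps. Vectors under 2 FPKM were compared with the asynchronous column, and the most frequent ratio in each column gave its relative depth. At 0 minutes, 107 of 863 low vectors were at that ratio and 33 at the next. With microRNA gene lengths from GENCODE release 29 (GRCh38), a 10 kb gene at 10 FPKM came to 24.6 such steps at 0 minutes and 45.97 in the asynchronous culture, a counting error of 20.2% and 14.7% if a step is 1 read. It covers counting alone, and captured fragments without molecular identifiers are not independent molecules.

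Gene lists were fixed before the data were examined, 22 in number with 809 symbols, of which 770 were present. The list of mitochondrially encoded genes had no member in the table and was not used here. The lists covered replication histones, ribosomal proteins, ribosome biogenesis, immediate early genes, heat shock genes, p53 targets, early G1 regulators, G1/S genes, mitotic genes, liver secreted proteins, liver transcription factors, cholesterol synthesis, the secretory pathway, oxidative phosphorylation, splicing, the cytoskeleton, adhesion and matrix genes, long noncoding RNAs, small structured RNAs, blood markers and stroma or endothelium markers. Each list's median was placed among 10000 random lists of its size drawn from 10 bins of mean expression, as a description of these columns.

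Genes to name were set by rule before the data were examined: the 10 largest differences in each direction for 0 minutes against the asynchronous culture and for 80 against 0 minutes, 5 for each other comparison and each first time at 2-fold, 4 members of each list, and RN7SK, MALAT1, ALB, AFP, FOS, CCNB1 and ACTB. The rule asked for agreement of 3 libraries and small adjusted p-values. Neither exists here, so genes were ranked by the size of the fold, with at least 5 FPKM in the higher group, and short or multicopy RNAs left out of the ranking. RN7SK was not among the kept genes. Because that ranking was led by genes near 0 FPKM, a ranking among protein-coding and long noncoding genes with at least 100 FPKM in the higher and 5 FPKM in the lower group was added after the data were seen, as were gene families by symbol and annotated RNA classes. No fold is given against a group listed at 0. Results of a few genes that met these rules were left out of the text.

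Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, quantile normalization and equal medians across groups. The highest transcript per gene and a filter of 10 FPKM were added after the data were seen. The fold counts were tested on a simulated pair of columns made from each gene's mean over the 7 groups, for 22940 genes. In each direction 200 genes were changed 4-fold, with an assumed noise of 0.2 on the log2 scale at every level. Of genes changed 4-fold 100% were counted. Of genes changed by 1.5-fold 8.50% were counted as 2-fold, and of unchanged genes 0.0403% were counted. The simulated noise did not grow at low levels, so these rates do not describe low genes. Gene lengths for the length tests were GENCODE spans, known for 94.97% of the kept genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.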

Results

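RNA made during a pulse of 5-ethynyl uridine (EU) was measured in HUH7 cells, an established human hepatoma line, after release from a mitotic block. EU is a uridine analogue that cells build into new transcripts, so that labelled RNA can be captured apart from older RNA. Cells held in mitosis with nocodazole, which blocks the spindle, were shaken off, replated and labelled at 0, 40, 80, 105, 165 or 300 minutes of release, and an asynchronous culture was labelled without a block. The pulse lasted 40 minutes, and whether a stated time marks its start or its end is not given in the sources used here, so the 0 minute values may include labelling early in the release. The labels list 3 samples for each of these 7 groups, with further unlabelled and spike-in groups that were not analysed here. Each group entered as the authors' single pooled value per transcript, so every difference compares 1 authors' value per group with another, with no replicate error and no replicate check. Summed over all transcripts, the values came to 6.24e+06 FPKM at 0 minutes, 7.60e+06 at 40, 1.04e+07 at 80, 1.06e+07 at 105, 9.96e+06 at 165, 9.06e+06 at 300 minutes and 8.80e+06 in the asynchronous culture. Relative to 0 minutes, the depth read from the steps between low values was 1.15 at 40 minutes, 1.49 at 80, 1.53 at 105, 1.75 at 165, 1.66 at 300 minutes and 1.87 in the asynchronous culture. Folds are ratios of FPKM + 1, and list medians are log2 folds relative to the median of all genes tested. A percentile places a list's median among 10000 random lists matched on expression. FPKM are scaled to the reads of a library, and the total used is not given in the sources used here. With the spike-in groups not analysed, a fold shows a level relative to other captured RNA, not the total amount of transcription.

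The comparison of 0 minutes with the asynchronous culture asks which genes were higher or lower, relative to other captured RNA, at or close to the mitotic block. Immediate early genes, which encode short-lived transcription factors and feedback regulators, stood above that culture. FOS was at 3819 FPKM at 0 minutes against 993 in the asynchronous culture, and its paralog FOSB, at 7246 FPKM, was 12.3-fold higher. The nuclear receptors NR4A1, NR4A2 and NR4A3 were 14.03, 10.4 and 52.5-fold higher, and the zinc finger factor KLF4 was 8.83-fold higher at 2581 FPKM. Of the 33 immediate early genes, 16 were at least 2-fold higher and 4 lower, with a median of 0.91 at percentile 100. Heat shock genes had a median of 0.57 at percentile 100, with 5 of 30 at least 2-fold higher and 0 lower: the chaperone gene HSPH1 was 3.68-fold higher, and HSPA1A stood at 6146 FPKM against 1753, although HSPA1A and HSPA1B are near-identical and can share reads. Among p53 targets, the cell cycle inhibitor CDKN1A was 16.1-fold higher at 333 FPKM, and the cell death genes BBC3 and PMAIP1 were 5.36 and 3.79-fold higher, in a list with 9 of 26 at least 2-fold higher and 1 lower.

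Single genes with high labelling at 0 minutes belonged to several other classes. CYP1B1, a cytochrome P450 of hormone and carcinogen metabolism, was at 1315 FPKM and 42.7-fold higher than in the asynchronous culture. The calcium-binding protein gene S100A6 was 32.1-fold higher, the parathyroid hormone-like gene PTHLH 26.5-fold higher, the small GTPase gene GEM 25.1-fold higher and the homeobox gene DLX2 24.8-fold higher. ACHE, which encodes acetylcholinesterase, was 20.5-fold higher, and the interferon-induced ISG15 was 15.4-fold higher at 698 FPKM. CD44, a hyaluronan receptor, was 8.52-fold higher. The fixed ranking was led by copies of the deubiquitinase family USP17L, whose reads cannot be told from one another; USP17L20 was at 103 FPKM and listed at 0 in the asynchronous culture. The neurosecretory gene VGF, at 223 against 1.42 FPKM, stood among them.

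Replication-dependent histone genes, which are transcribed in S phase, were far lower at 0 minutes than in the asynchronous culture, with 36 of 45 at least 2-fold lower, a median of -4.22 and percentile 0. The linker histone genes H1-1 and H1-4 were at 5.75 and 7.69 FPKM against 2233 and 1789.5, and H1-5 was at 0.0683 against 2212. The core histone gene H3C2 was at 1.06 against 1969 FPKM. Histone genes share sequence, so the split of reads between copies is uncertain. Genes of the G1/S transition were lower at 32 of 40, with a median of -1.49 at percentile 0: the thymidylate synthase gene TYMS was 8.40-fold lower, the replication factor GINS2 7.92-fold lower, the helicase subunit MCM6 6.98-fold lower and the uracil glycosylase UNG 6.73-fold lower. Mitotic genes were nearer to the asynchronous level, with 12 of 40 at least 2-fold lower, a median of -0.50 and percentile 32.2. Cyclin B1 gene CCNB1 was at 619.7 against 561 FPKM, whereas the mitotic kinase gene AURKB was 2.64-fold lower and the transcription factor FOXM1 2.99-fold lower. AURKB and FOXM1 were under 2-fold after quantile normalization.

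Many liver identity genes were lower at 0 minutes than in the asynchronous culture. AFP, the fetal serum protein alpha-fetoprotein, was at 133 FPKM against 3964, and albumin, ALB, at 128 against 2295. The iron carrier TF was 23.1-fold lower and the plasma glycoprotein gene AHSG 19.5-fold lower. Of 52 genes for liver secreted and metabolic proteins, 26 were at least 2-fold lower and 7 higher, at a median of -0.87 and percentile 0. The liver transcription factor CEBPA was 75.8-fold lower, ONECUT1 10.7-fold lower, the pioneer factor FOXA1 7.71-fold lower and the bile acid receptor NR1H4 7.44-fold lower, within a list median of -0.81 at percentile 0.09 (1 of 27 at least 2-fold higher, 11 lower). The tubulin genes TUBB and TUBA1A were 10.2 and 7.35-fold lower.

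Other list medians at 0 minutes against the asynchronous culture were -0.40 (0.05 after quantile normalization) for ribosomal proteins at percentile 24.6, -0.60 for ribosome biogenesis at percentile 3.62, -0.67 for long noncoding RNAs at percentile 0.73 and 0.18 for early G1 regulators at percentile 98.98. They were -0.38 (0.10 after quantile normalization) for nuclear oxidative phosphorylation genes, -0.37 (0.05 after quantile normalization) for splicing factors, -0.21 (0.26 after quantile normalization, 0.05 with the 10 FPKM filter) for the secretory pathway, -0.25 (0.24 after quantile normalization, 0.01 with the 10 FPKM filter) for cholesterol synthesis, -0.35 (0.07 after quantile normalization) for the cytoskeleton, -0.29 (0.04 after quantile normalization) for adhesion and matrix genes and 0.23 for p53 targets at percentile 99.9. Percentiles were 77.8 for oxidative phosphorylation, 44.7 for splicing, 50.7 for the cytoskeleton and 57.5 for adhesion. They were 94.1 for the secretory pathway and 84.3 for cholesterol synthesis, above most matched lists although their medians were below 0. Small structured RNAs stood at -0.29 relative to all genes, at percentile 30.4. Their log2 folds as deposited had a median of -0.43 but a mean of 0.06. The vault RNA gene VTRNA1-1 was 4.32-fold higher and the minor spliceosome RNA RNU11 4.35-fold lower. Markers of blood cells and of stroma or endothelium, which a hepatoma culture should lack, stood at 0.97 and 0.70, with percentiles 97.1 and 76.9, from low levels such as 27.3 FPKM of CD79A and 25.4 of COL1A1.

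Across 22940 genes, 3239 were at least 2-fold higher and 4349 lower at 0 minutes than in the asynchronous culture, around an all-gene median log2 fold of -0.14. The higher share of the counted genes was 42.7% as deposited, 53.6% relative to the all-gene median, 50.2% after quantile normalization, 69.2% with equal medians and 32.4% in genes of at least 10 FPKM in 3 groups. Every release group had passed through thymidine, nocodazole and shake-off, so the block and the cell cycle stage cannot be separated in a comparison with the asynchronous culture.

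**Figure D1:**
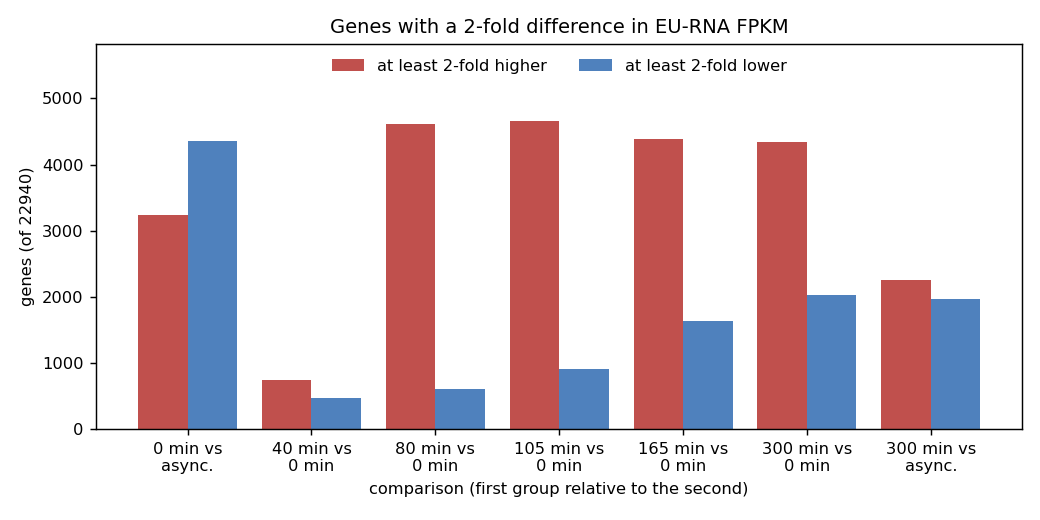
Number of genes at least 2-fold higher (red bars) or lower (blue bars) in the first group than in the second group of each of 7 comparisons, from the authors' FPKM as deposited. Counts of higher genes stood between 4335 and 4657 from 80 minutes on against 743 at 40 minutes, a balance that moved with the scaling.

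At 40 minutes against 0 minutes, the question is which genes rose first relative to other captured RNA. Differences in FPKM were few, with 743 genes at least 2-fold higher and 470 lower around an all-gene median of 0.10. A change common to all genes could be missed by these counts. Ribosomal protein genes had the highest median of the lists, at 0.44 and percentile 100 (4 of 78 at least 2-fold higher, 0 lower): RPS28 was 4.11-fold higher at 240.0 FPKM, RPL36 2.72-fold higher, RPL10 2.12-fold higher and RPS21 2.10-fold higher. The TFIID subunit gene TAF10 was 3.13-fold higher and the splicing factor gene SF3B5 3.20-fold higher, but 0 of 48 genes in the splicing list were at least 2-fold higher. The tubulin gene TUBA1A was 3.98-fold higher, the actin gene ACTG1 2.25-fold higher and the actin severing gene CFL1 1.84-fold higher. The respiratory chain genes ATP5F1D and UQCRQ were 2.26 and 2.16-fold higher. Among replication histones, H1-1 was 8.80-fold higher and H2AC4 6.15-fold higher, and 15 of 45 genes were at least 2-fold higher, at a median of 0.28. RPL10, RPS21, ACTG1 and UQCRQ were under 2-fold after quantile normalization, and RPL10 and RPS21 also with equal medians.

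Of the immediate early genes at 40 minutes, 1 of 33 was at least 2-fold above 0 minutes and 0 lower, although 16 had their highest value of the release. NR4A2 was 1.93-fold higher, the matrix protein gene CCN2 1.70-fold higher and the antiproliferative gene BTG2 1.61-fold higher, within a median of 0.30 at percentile 98.9. CDKN1A was 1.92-fold higher at 642 FPKM and the exonuclease gene AEN 2.17-fold higher, within a p53 target median of 0.25 at percentile 99.8 (1 of 26 at least 2-fold higher, 0 lower). CEBPA was 3.05-fold higher, CEBPD 2.27-fold higher and the fibrinogen gene FGA 2.24-fold higher at 1197 FPKM. The gluconeogenic enzyme gene PCK1 was 2.14-fold higher, while APOA1 was 1.73-fold lower. Among liver factors 2 of 27 were at least 2-fold higher and 0 lower, at a median of 0.07 and percentile 47.9. Among liver secreted genes 3 of 52 were at least 2-fold higher and 0 lower, at a median of 0.07 and percentile 94.6. Mitotic genes at 40 minutes (0 of 40 at least 2-fold higher, 0 lower) had a median of 0.02 (-0.12 after quantile normalization, -0.02 with the 10 FPKM filter), with AURKB 1.63-fold higher. Heat shock genes (0 of 30 at least 2-fold higher, 0 lower) had a median of 0.01 (-0.20 after quantile normalization, -0.04 with the 10 FPKM filter), below nearly all matched lists at percentile 0.01, and their mean log2 fold of 0.08 lay below the all-gene median. Long noncoding RNAs (0 of 23 at least 2-fold higher, 0 lower) stood at 0.32 with percentile 99.2, with the small nucleolar RNA host DANCR 1.53-fold higher. The fixed ranking was led by pseudogenes and genes near 0 FPKM, such as UBE2MP1 at 25.4 against 0.151 FPKM and the chemokine gene CCL27 at 27.2 FPKM and listed at 0 FPKM at 0 minutes. AEN and FGA were under 2-fold after quantile normalization.

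At 80 minutes, replication histone genes had the highest median of the lists against 0 minutes. H1-1 was 184-fold higher at 1239 FPKM, H1-4 130.1-fold higher at 1129.6 and H2AC4 173-fold higher at 791 FPKM. H3C2 was at 425 FPKM against 1.06 at 0 minutes. Of 45 genes, 40 were at least 2-fold higher and 0 lower, with a median of 2.15 at percentile 100. Members differed in how close they came to the asynchronous level: H1-5 was at 4.28 FPKM against 2212 and H2BC8 at 1516 against 2402, while some, such as H4C1 at 1227 against 379.8, were above it. Many H2B and H3 copies share sequence, so values of single members are uncertain.

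Ribosomal protein genes were at least 2-fold higher at 48 of 78, with a median of 0.77 at percentile 100 and the highest value of the release at 80 minutes for 53. RPS28 was 5.22-fold higher, RPS21 4.34-fold higher, RPS25 3.96-fold higher and RPL13 3.47-fold higher. Ribosome biogenesis genes (19 of 49 at least 2-fold higher, 0 lower) had a median of 0.53 at percentile 69.2, with the rRNA processing gene BOP1 3.03-fold higher and the RNA polymerase I subunit POLR1B 2.94-fold higher. Respiratory chain genes (21 of 52 at least 2-fold higher, 0 lower) stood at 0.52 with UQCRQ 3.57-fold higher and COX8A 3.15-fold higher. Splicing factors (18 of 48 at least 2-fold higher, 0 lower) stood at 0.50 with PRPF4 2.56-fold higher. In the secretory pathway, the translocon gene SSR3 was 2.67-fold higher within a median of 0.42 (-0.04 after quantile normalization) (12 of 45 at least 2-fold higher, 0 lower). Percentiles of these last 3 lists were 75.1, 46.1 and 20.3. Cholesterol genes (9 of 28 at least 2-fold higher, 0 lower), at a median of 0.39 (-0.01 after quantile normalization) and percentile 27.5, included the sterol sensors INSIG2 and INSIG1, 4.51 and 2.55-fold higher. Tubulin genes TUBA1A and TUBB were 9.02 and 3.83-fold higher within a cytoskeleton median of 0.46 (-0.05 after quantile normalization) (10 of 41 at least 2-fold higher, 0 lower). RPL13, POLR1B, PRPF4, SSR3 and INSIG1 were under 2-fold after quantile normalization, and PRPF4 and INSIG1 also with equal medians.

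Some G1 regulators were higher at 80 minutes, 7 of 18 by at least 2-fold. The inhibitor CDKN2C was 7.86-fold higher and the MYC family gene MYCN 4.83-fold higher, within an early G1 median of 0.56 at percentile 85.1. PCNA, the sliding clamp of DNA replication, was 5.10-fold higher at 925 FPKM, and UNG was 3.97-fold higher, within a G1/S median of 0.27 (-0.04 after quantile normalization) at percentile 26.2, where 7 of 40 were at least 2-fold higher. The p53 targets SESN1 and RRM2B were 2.91 and 2.73-fold higher within a median of 0.46 at percentile 69.5 (10 of 26 at least 2-fold higher, 0 lower). FOXA1 was 4.98-fold higher at 1069 FPKM and CEBPA 4.06-fold higher, within a liver factor median of 0.20 (-0.21 after quantile normalization) (6 of 27 at least 2-fold higher, 0 lower). The liver secreted list (0 of 52 at least 2-fold higher, 2 lower) had a median below that of all genes, at -0.43 and percentile 0: FGA was 3.30-fold lower and its partner FGG 2.01-fold lower. ALB was at 166 against 128 FPKM and AFP at 182 against 133, both differences changing sign after quantile normalization and that of ALB also with equal medians. FOS was 2.12-fold lower, while the kinase gene SGK1 was 3.26-fold higher, within an immediate early median of -0.08 at percentile 0 (3 of 33 at least 2-fold higher, 1 lower). Mitotic genes (0 of 40 at least 2-fold higher, 0 lower) stood at -0.19 relative to all genes and percentile 0. Their median log2 fold as deposited was 0.12, and 18 of 40 had their highest value of the release at 80 minutes. CDK1 was 1.66-fold lower, while BUB3, at 1.88-fold higher, changed sign after quantile normalization. CCNB1, at 701 FPKM, changed sign there and with equal medians. Actin gene ACTB, at 434 FPKM, was 1.71-fold higher as deposited and lower after quantile normalization. SESN1, RRM2B and SGK1 were under 2-fold after quantile normalization.

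Other lists at 80 minutes had medians of 0.06 (-0.27 after quantile normalization, -0.05 with the 10 FPKM filter) for adhesion and matrix genes, -0.09 for heat shock genes, 0.44 for long noncoding RNAs, 0.21 (-0.02 with the 10 FPKM filter) for small structured RNAs, -0.40 (0.03 after quantile normalization) for blood markers and -0.53 for stroma and endothelium markers. The adhesion median, though above 0, lay at percentile 0.65. The minor spliceosome RNA RNU6ATAC was 39.1-fold higher at 109.9 FPKM. In all, 4613 genes were at least 2-fold higher and 609 lower around an all-gene median of 0.31. The higher share was 88.3% as deposited, 66.8% relative to the all-gene median, 59.5% after quantile normalization and 57.5% with equal medians.

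**Figure D2:**
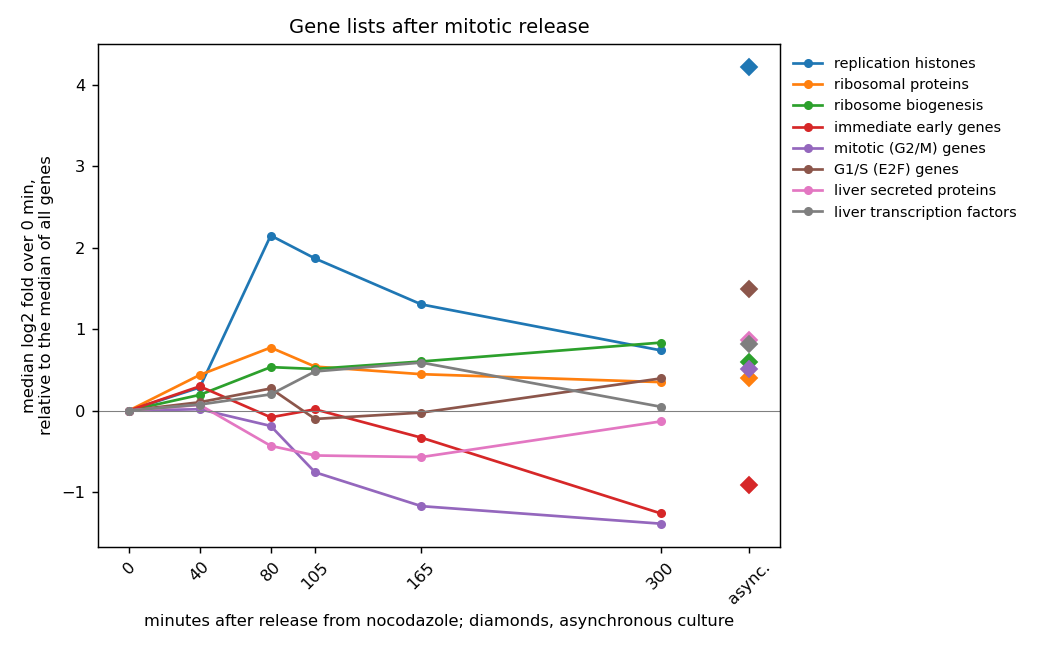
Median log2 fold over 0 minutes of 8 gene lists, relative to the median of all genes, against minutes after release (lines), with the asynchronous culture as diamonds. Replication histones reached 2.15 at 80 minutes and mitotic genes -1.39 at 300 minutes. The medians of G1/S genes and liver factors at 80 and 300 minutes changed sign after quantile normalization. So did those of ribosomal proteins at 165 and 300 minutes and in the asynchronous culture. Immediate early genes at 105 minutes and mitotic genes at 40 minutes also changed sign there, and G1/S genes at 165 minutes with no filter.

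At 105 minutes, early G1 regulators stood out from 0 minutes at a median of 0.71 and percentile 99.02 (10 of 18 at least 2-fold higher, 0 lower). MYCN was 8.53-fold higher, cyclin D1 gene CCND1 3.32-fold higher and MAX, the partner of MYC, 3.06-fold higher. CSF1, a macrophage growth factor gene, and the cytokine gene TNF first reached 2-fold at this time, at 5.59 and 5.26-fold higher, with CSF1 at 736 FPKM. Liver transcription factors (11 of 27 at least 2-fold higher, 0 lower) had a median of 0.48 at percentile 92.9, with CEBPA 5.51-fold higher, FOXA1 4.55-fold higher and ONECUT2 3.91-fold higher. The liver secreted list had a median of -0.55 at percentile 0, but 3 of 52 genes were at least 2-fold higher and 2 lower: FGA was 4.29-fold lower and ITIH2 2.09-fold lower, while the drug-metabolising CYP3A5 was 3.16-fold higher. ALB and AFP, at 165 and 192 FPKM, were above 0 minutes as deposited and below after quantile normalization. Integrin ITGA5 was 2.73-fold higher and the junction gene CTNNB1 2.28-fold higher, within an adhesion median of 0.37 (10 of 38 at least 2-fold higher, 0 lower). CCND1, MAX, ITGA5 and CTNNB1 were under 2-fold after quantile normalization, and CTNNB1 also with equal medians.

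At 105 minutes 5 of 40 mitotic genes were at least 2-fold lower and 0 higher, with a median of -0.76 at percentile 0. CDK1 was 2.69-fold lower, the ubiquitin ligase partner UBE2C 2.68-fold lower, the topoisomerase TOP2A 2.42-fold lower and AURKB 2.41-fold lower. The formin gene DIAPH3, which acts in cytokinesis, was 3.05-fold lower. FOS was 3.54-fold lower, but 15 immediate early genes had their highest value at 105 minutes, among them EGR2 at 2.71-fold higher. Their list median was 0.02 (-0.19 after quantile normalization, -0.18 with the 10 FPKM filter) at percentile 0 (7 of 33 at least 2-fold higher, 3 lower), and their mean log2 fold of 0.26 lay below the all-gene median of 0.37. Replication histones (39 of 45 at least 2-fold higher, 0 lower) stood at 1.87, with H1-4 106-fold higher and H4C5 13.9-fold higher. Respiratory genes (20 of 52 at least 2-fold higher, 0 lower) stood at 0.56 with COX7C 3.38-fold higher, and secretory genes (15 of 45 at least 2-fold higher, 0 lower) at 0.53 with SEC61G 2.82-fold higher. Cholesterol genes (1 of 28 at least 2-fold higher, 0 lower) were at 0.16 (-0.24 after quantile normalization, -0.06 with the 10 FPKM filter), a median above 0 that lay at percentile 0.05, and heat shock genes (0 of 30 at least 2-fold higher, 3 lower) at -0.30. Counts were 4657 higher and 916 lower, a higher share of 83.6% as deposited, 43.9% relative to the all-gene median, 54.8% after quantile normalization and 39.5% with equal medians. EGR2, COX7C and SEC61G were under 2-fold after quantile normalization.

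By 165 minutes several immediate early genes were far below their level at 0 minutes. NR4A1 was 9.25-fold lower, FOS 8.38-fold lower, the AP-1 gene JUND 4.64-fold lower and KLF2 3.71-fold lower, within a median of -0.33 at percentile 0 (1 of 33 at least 2-fold higher, 9 lower). Mitotic genes stood at -1.17 and percentile 0, with 18 of 40 at least 2-fold lower. AURKB was 4.68-fold lower at 66.7 FPKM, and HJURP, which loads the centromeric histone, 3.75-fold lower. The G1 genes MYCN, CDK6 and MYC were 9.85, 3.91 and 2.85-fold higher, with MYC at 4341 FPKM. ONECUT2 was 4.66-fold higher, within a liver factor median of 0.59 at percentile 96.9 (11 of 27 at least 2-fold higher, 2 lower). AFP was 4.33-fold higher at 579 FPKM and CYP3A5 5.81-fold higher. The list of secreted genes split into 9 higher and 5 lower, with a median of -0.57 at percentile 0. MYC was under 2-fold after quantile normalization.

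Several genes of adhesion and the cytoskeleton were higher at 165 minutes. The integrin gene ITGA2 was 3.15-fold higher, N-cadherin gene CDH2 2.82-fold higher and tropomyosin gene TPM1 4.19-fold higher, while ACTG1 was 2.52-fold lower. The list medians were 0.45 at percentile 70.01 for adhesion (13 of 38 at least 2-fold higher, 1 lower) and 0.26 (-0.21 after quantile normalization) at percentile 0.36 for the cytoskeleton (6 of 41 at least 2-fold higher, 1 lower). Steroid reductase gene AKR1C2 was 7.88-fold higher, the fatty acid enzyme gene ACSL5 4.53-fold higher and the protocadherin PCDHGA9 4.71-fold higher. Ribosome biogenesis (20 of 49 at least 2-fold higher, 0 lower) stood at 0.60 with POLR1B 3.32-fold higher, and the noncoding FTX and JPX were 2.85 and 2.60-fold higher in a list at 0.10 (-0.08 after quantile normalization, -0.12 with the 10 FPKM filter) (5 of 23 at least 2-fold higher, 1 lower). INSIG1 was 2.07-fold lower, within a cholesterol median of -0.49 at percentile 0 (1 of 28 at least 2-fold higher, 2 lower). HSPA1A was 3.63-fold lower, within a heat shock median of -0.45 (0 of 30 at least 2-fold higher, 6 lower). The p53 targets (3 of 26 at least 2-fold higher, 0 lower) stood at 0.06 (-0.41 after quantile normalization, -0.19 with the 10 FPKM filter), a median above 0 at percentile 0.36. Counts were 4388 higher and 1631 lower around an all-gene median of 0.26. The higher share was 72.9% as deposited, 44.5% relative to the all-gene median, 49.04% after quantile normalization, 37.9% with equal medians and 83.4% in genes of at least 10 FPKM in 3 groups. ITGA2, CDH2, POLR1B, FTX and JPX were under 2-fold after quantile normalization.

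At 300 minutes, immediate early genes had their lowest median of the release. NR4A1 was 32.8-fold lower at 52.6 FPKM, NR4A3 33.6-fold lower, FOS 26.9-fold lower, FOSB 19.9-fold lower, the stress factor ATF3 12.4-fold lower and EGR3 8.01-fold lower. Of the list, 19 of 33 were at least 2-fold lower, at a median of -1.26 and percentile 0. Mitotic genes (0 of 40 at least 2-fold higher, 25 lower) stood at -1.39, with TOP2A 4.21-fold lower, UBE2C 3.96-fold lower, the kinesin KIF18A 3.80-fold lower and the checkpoint target CDC20 3.73-fold lower. Higher genes included the steroid reductases AKR1C1 and AKR1C2, 12.9 and 16.3-fold higher, which are close paralogs. PLCXD3, a phospholipase-like gene, was 29.03-fold higher, the guidance cue SEMA3D 12.4-fold higher, the sphingolipid enzyme SPTLC3 11.3-fold higher, the vesicle gene RAB27B 11.2-fold higher and the decoy receptor TNFRSF11B 10.3-fold higher at 1039 FPKM.

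Some replication and liver genes were higher at 300 minutes than at 0 minutes. UNG was 8.51-fold higher, the helicase subunit MCM5 4.44-fold higher and GINS2 2.79-fold higher. The G1/S list (10 of 40 at least 2-fold higher, 0 lower) had a median of 0.39 (-0.002 after quantile normalization). It lay at percentile 38.1, so the list as a whole did not stand above matched lists. AFP was 8.06-fold higher, ALB 5.16-fold higher and the clotting factor gene F5 4.91-fold higher. The liver secreted list split into 14 genes higher and 8 lower, with a median of -0.13 and a mean log2 fold of 0.26 that lay above the all-gene median of 0.21. The xenobiotic receptor NR1I2 was 3.25-fold higher, within a liver factor median of 0.05 (-0.33 after quantile normalization, -0.20 with the 10 FPKM filter) (6 of 27 at least 2-fold higher, 2 lower). Ribosome biogenesis had its highest median of the release, at 0.83 and percentile 99.97 (26 of 49 at least 2-fold higher, 0 lower), with POLR1B 4.49-fold higher, RRP9 3.33-fold higher and HEATR1 3.25-fold higher. Histone genes (18 of 45 at least 2-fold higher, 4 lower) still stood at 0.74 with H1-4 31.01-fold higher, whereas H4C1 was 5.15-fold lower. Cholesterol genes INSIG1, MVD and IDI1 were 3.02, 2.65 and 2.35-fold lower, within a median of -0.40 at percentile 0 (0 of 28 at least 2-fold higher, 4 lower). ID1 was 5.24-fold lower and CDKN1A 2.71-fold lower, within an early G1 median of -0.51 (4 of 18 at least 2-fold higher, 5 lower). Counts were 4335 higher and 2024 lower, a higher share of 68.2% as deposited, 48.7% relative to the all-gene median, 49.4% after quantile normalization and 33.4% with equal medians.

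**Figure D3:**
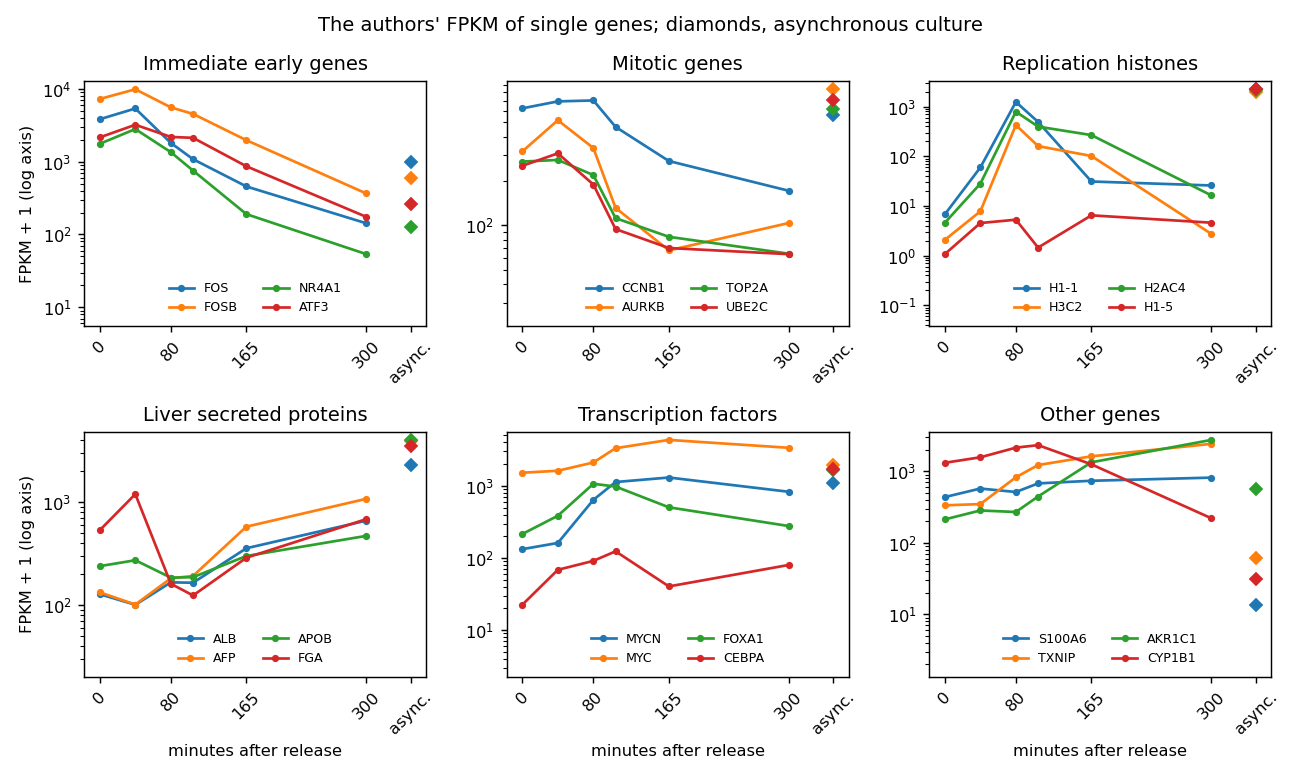
FPKM + 1 of single genes (log axis) against minutes after release, in 6 panels by gene class, with the asynchronous culture as diamonds. FOS stood at 5363 FPKM at 40 minutes and 141 at 300 minutes, and AFP at 1078 at 300 minutes against 3964 in the asynchronous culture, while ALB and AFP at 80 and 105 minutes and CCNB1 at 40 and 80 minutes changed sign against 0 minutes after quantile normalization.

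The comparison of 300 minutes with the asynchronous culture asks how far cells late in the release remained from an unsynchronised culture. Mitotic genes were lower at 32 of 40, at a median of -1.82 and percentile 0, with UBE2C 11.04-fold lower, TOP2A 9.55-fold lower, AURKB 8.05-fold lower and the spindle gene ASPM 6.999-fold lower. Replication histones (1 of 45 at least 2-fold higher, 31 lower) stood at -3.53, with H1-1 at 24.8 FPKM against 2233. G1/S genes (0 of 40 at least 2-fold higher, 25 lower) stood at -1.28, with the ribonucleotide reductase subunit RRM2 11.5-fold lower, the thymidine kinase TK1 5.13-fold lower and cyclin E1 gene CCNE1 4.63-fold lower. Liver secreted genes were lower at 24 of 52 and higher at 2, a median of -0.82 at percentile 0. The protease inhibitor ITIH2 was 37.4-fold lower, the acute phase gene ORM1 16.2-fold lower, AHSG 13.7-fold lower, haptoglobin gene HP 11.5-fold lower and ALB 3.46-fold lower. CEBPA was 21.2-fold lower and ONECUT1 8.55-fold lower, within a liver factor median of -0.54 (2 of 27 at least 2-fold higher, 9 lower).

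The immediate early list split at 300 minutes against the asynchronous culture, with 9 of 33 at least 2-fold lower and 5 higher, at a median of -0.69 and percentile 0. EGR1 was 8.01-fold lower and CCN2 6.96-fold lower. Cholesterol genes (1 of 28 at least 2-fold higher, 7 lower) stood at -0.71 with the acetyl-CoA enzyme gene ACAT2 2.55-fold lower. Several genes that were high at 0 minutes were also high at 300 minutes: S100A6 was 59.98-fold higher, GEM 22.3-fold higher, CD44 14.7-fold higher and CDKN1A 5.93-fold higher. The p53 target median was 0.38 at percentile 99.49 (6 of 26 at least 2-fold higher, 1 lower). TXNIP, a redox regulator, was 39.6-fold higher at 2422 FPKM, the retinoic acid-induced receptor GPRC5A 16.7-fold higher, the anchoring collagen COL7A1 20.8-fold higher and keratin gene KRT19 5.50-fold higher. Ribosome biogenesis (1 of 49 at least 2-fold higher, 1 lower) stood at 0.24 and percentile 98.6, while ribosomal proteins at -0.08, splicing factors at 0.04, respiratory genes at -0.04 (0.03 after quantile normalization) and secretory genes at -0.01 (0.06 after quantile normalization, 0.01 with no filter) lay near all genes. Stroma and endothelium markers had a median log2 fold of -0.04 but a mean of 0.45. Relative to all genes their median was -0.15, but 1.4995 with the 10 FPKM filter and 0.04 with no filter. Counts were 2258 higher and 1965 lower around an all-gene median of 0.11.

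Over the 6 release times, 13117 genes (57.2%) had a range of at least 2-fold. Their highest value was at 80 minutes for 3658 and at 300 minutes for 3084, and their lowest at 0 minutes for 5483. Ever 2-fold above 0 minutes were 8603 genes, of which 743 first passed at 40 minutes, 4141 at 80, 1305 at 105, 1410 at 165 and 1004 at 300 minutes. With equal medians these were 4571 genes, with 623, 1738, 489, 994 and 727 in the same order. Genes leading the first group at 40 minutes were ATP6V0CP3, CCL27, UBE2MP1, CYCSP52 and ANKRD36BP1, mostly pseudogenes close to 0 FPKM at 0 minutes. H2BC7, H1-4, H2BC3 and H2BC4 led at 80 minutes and KRTAP22-1, CSF1 and TNF at 105 minutes. OR1L8, NPFF, PLCXD3, PCDHGA9 and ACSL5 led at 165 minutes, and at 300 minutes LINC01526, the aminoacylase gene ACY3 at 134 FPKM and the creatine kinase gene CKMT1A at 16.2. Still 2-fold above 0 minutes at 300 minutes were 50.1% of genes first at 40 minutes, 30.9% of those first at 80, 52.8% at 105 and 70.2% at 165 minutes. The abundant nuclear RNA MALAT1 stood at 4917 FPKM at 0 minutes, 6911 at 40 and 3604 at 300 minutes, and 2408 in the asynchronous culture.

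Genes first 2-fold above 0 minutes at 165 minutes were longer than those first at 40 minutes. Median lengths of protein-coding genes were 3.36 kb for those first at 40 minutes, 15.98 kb at 80, 34.2 kb at 105, 56.5 kb at 165 and 45.4 kb at 300 minutes, against 36.01 kb for genes that never passed. Genes first at 40 minutes also had a median of 7.58 FPKM at 0 minutes, against 93.1 for those first at 165 minutes.

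**Figure D4:**
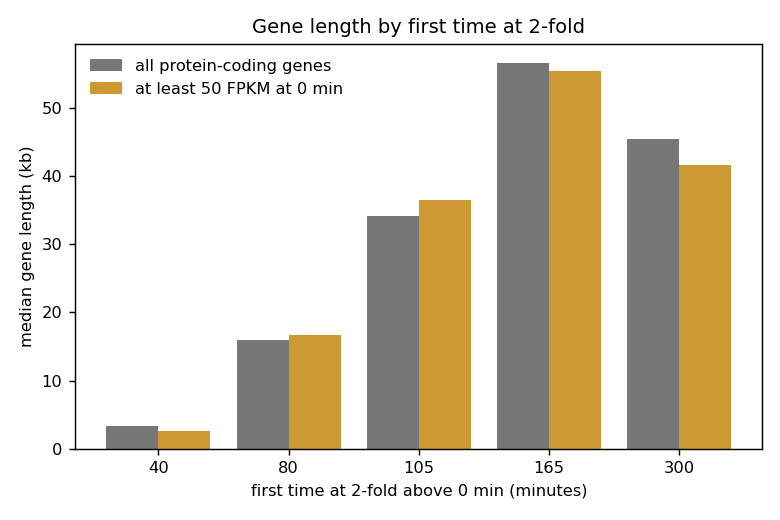
Median gene length in kb of protein-coding genes by the first time at which they were 2-fold above 0 minutes, for all such genes (grey bars) and for genes of at least 50 FPKM at 0 minutes (ochre bars). Medians ran from 3.36 kb at 40 minutes to 56.5 kb at 165 minutes, and in the second group from 2.62 to 55.3 kb.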

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

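The alternatives with the highest transcript per gene and with a filter of 10 FPKM were tests chosen only after the result was seen. No paired analysis was possible because the columns carry no replicate letters and each holds 1 pooled value. For the same reason, leaving out replicates, a fit of the 2 compared groups alone, a replicate block, a filter against the unlabelled control and camera with its alternatives were not run.

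Of 20 counts of genes, all stayed within 1.5 times of the main count with a pseudocount of 0.1, with no filter and with the highest transcript per gene. Over all 6 alternatives 91 count values stayed within 1.5 times and 29 did not. At 0 minutes against the asynchronous culture, higher genes numbered 5492 with equal medians and 1961 with the 10 FPKM filter, and lower genes 2715 after quantile normalization and 2447 with equal medians. Against 0 minutes, quantile normalization gave 1608 higher and 1094 lower genes at 80 minutes, and 1458, 1688 and 2233 higher genes at 105, 165 and 300 minutes. Equal medians gave 2090 higher and 1542 lower at 80 minutes, 1707 and 2619 at 105, 2100 and 3435 at 165, and 2166 and 4317 at 300 minutes. With the 10 FPKM filter, 457 genes were higher and 224 lower at 40 minutes, and lower genes numbered 239, 364, 820 and 1187 from 80 to 300 minutes. Genes first at 2-fold numbered 457 at 40 minutes under that filter, which tests fewer genes. They numbered 1199, 415 and 682 at 80, 105 and 165 minutes after quantile normalization, and 1738 and 489 at 80 and 105 minutes with equal medians. Equal medians give every column the same median level, which is not a centring of the folds: relative to the all-gene median fold, 4025 genes were higher and 3487 lower at 0 minutes than in the asynchronous culture, and 2987 and 3144 at 300 against 0 minutes. The cause of these moves was not tested.

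Of 147 list medians, 19 values under an alternative had the other sign in a list that stood outside the central 95% of matched lists, and the cause was not tested. After quantile normalization and with the 10 FPKM filter, respectively, they were -0.27 and -0.0529 for adhesion at 80 minutes against 0.06, -0.24 and -0.0616 for cholesterol at 105 minutes against 0.16, -0.24 and -0.18 for the cytoskeleton at 300 minutes against 0.07, -0.20 and -0.0356 for heat shock at 40 minutes against 0.01. They were -0.19 and -0.18 for immediate early genes at 105 minutes against 0.02, -0.0819 and -0.12 for long noncoding RNAs at 165 minutes against 0.10, -0.12 and -0.0223 for mitotic genes at 40 minutes against 0.02, and -0.41 and -0.19 for p53 targets at 165 minutes against 0.06. Quantile normalization alone gave -0.21 for the cytoskeleton at 165 minutes against 0.26 and -0.0653 for long noncoding RNAs at 105 minutes against 0.25, and no filter gave 0.0289 for G1/S genes at 165 minutes against -0.02. Of the other list values 644 lay within 0.1 of the main value and 219 did not. Of the former, 147 came with equal medians, which move all genes of a column alike and could hardly change a median relative to all genes, so they are no test of it.

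For 790 folds of named genes, 4401 values kept their side of 2-fold and 282 did not, and none past 2-fold changed sign. Of those that moved, 184 came with quantile normalization and 94 with equal medians. Depth limits low genes most, and 1 value per group leaves differences near 2-fold open.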

Other observations

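The gene families and RNA classes, the length test in genes of at least 50 FPKM and the S phase test for histones were tests chosen only after the result was seen. Of 11 families looked at, zinc finger genes and protocadherins had high values late in the release. At 300 against 0 minutes olfactory receptor genes also lay at percentile 100, with 33 of 90 at least 2-fold higher and 10 lower. Keratin-associated genes lay at percentile 99.84, with 8 of 18 higher and 4 lower. A high percentile alone therefore did not set zinc finger genes and protocadherins apart. Zinc finger genes, 499 in number and mostly encoding DNA-binding proteins, stood at 0.39 (0.14 after quantile normalization) relative to all genes at 80 minutes, 0.61 (0.35 after quantile normalization) at 165 and 0.76 (0.49 after quantile normalization) at 300 minutes, with 240 at least 2-fold higher and 8 lower than at 0 minutes. Against the asynchronous culture the family stood at 0.38 (0.44 after quantile normalization) at 300 minutes, with percentile 100. The 52 protocadherin genes, which encode adhesion molecules from clustered promoters that share exons and therefore reads, were lower at 36 at 0 minutes than in the asynchronous culture, with a median of -1.39 (-1.22 after quantile normalization). At 300 minutes 37 were at least 2-fold higher than at 0 minutes, with a median of 1.64, or 1.52 after quantile normalization. PCDHGB6 stood at 24.1 FPKM at 0 minutes, 271 at 300 minutes and 148 in the asynchronous culture.

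Mitochondrial ribosomal protein genes stood at -0.72 (-0.23 after quantile normalization) at 0 minutes against the asynchronous culture and at 0.54 (0.19 after quantile normalization) at 80 minutes against 0 minutes. The tRNA synthetase genes stood at 0.67 (0.28 after quantile normalization) at 165 and 0.73 (0.33 after quantile normalization) at 300 minutes. Annotated small nuclear RNA genes, 35 multicopy genes with uncertain values, stood at 1.76 (1.87 after quantile normalization) at 0 minutes relative to all genes, with 20 at least 2-fold higher and 4 lower than in the asynchronous culture. Small nucleolar RNA genes stood at 0.53 (0.19 after quantile normalization) at 80 minutes. Long noncoding genes as a class stood at 0.43 at 0 minutes against the asynchronous culture, but at -0.06 after quantile normalization.

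The first time at which a gene was 2-fold above 0 minutes went with gene length. Across protein-coding genes, which are not independent replicates, the Spearman correlation of length with first time was 0.444, where a value below 0.1 would have spoken against length. Among 4676 genes of at least 50 FPKM at 0 minutes it was 0.409, with a bootstrap interval of 0.382 to 0.435. That interval resampled genes and holds no replicate error. At a given FPKM a shorter gene can have fewer reads, so the cut did not remove counting noise tied to length. Low level at 0 minutes stayed open as a source too, since the median level of genes first at 40 minutes was 0.0813 of that of genes first at 165 minutes, and 49 genes of at least 50 FPKM came first at 40 minutes. Median length rose with first time up to 165 minutes, at 56.5 kb, but was 45.4 kb for genes first at 300 minutes. Both correlations used the values as deposited, where 4141 genes came first at 80 minutes, against 1199 after quantile normalization. Whether the time needed to transcribe long genes plays a part was not tested, nor were separate waves of activation by promoter.

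Histone genes at 80 minutes were weighed against S phase cells mixed into the culture, which would bring each gene to a like share of its asynchronous level. The share gained had an interquartile range of 54.5 percentage points over 36 genes, where a mixture needed under 10 points. The quartiles were 11.6% and 66.1%, with 7 genes under 5% and 14 over 50%. Single shares ran from -0.02% for H2BC17 to 436.6% for H4C1. Values of single histone copies are uncertain and could widen the range by themselves, so it cannot decide against S phase cells. A first version over 41 genes gave 75.05 points, but 2 of them had no gain to share, and the set was narrowed to genes at least 2-fold lower at 0 minutes after that value was seen. Against short length, the list's median lay at percentile 100 of length-matched random lists. Those lists were drawn from all RNA classes, and short genes there include many of the 913 microRNA and 224 small nucleolar RNA genes. The matched lists were therefore not short protein-coding genes alone, and an effect of short length among such genes was not excluded. S phase cells in the culture stayed open. Reads shared between copies and early G1 transcription of some histone genes remain candidate explanations that were not tested.

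Liver secreted genes below the asynchronous level at 300 minutes were weighed against carry-over of abundant unlabelled mRNA in the asynchronous pull-down. Carry-over larger in the asynchronous pull-down would also lower other abundant stable mRNAs at 300 minutes, with ribosomal protein genes under -0.5. Their median was -0.0797 relative to all genes, with an interval from resampling the list's genes of -0.14 to -0.01. Carry-over alike in both pull-downs would not move that median, and the unlabelled control that could measure it was not analysed here. Gene length was argued against by a percentile of 0 among length-matched lists. The difference in cell cycle stage and the drug block, which every release group shared, stayed open as untested, since the design cannot separate them.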
